A study of Caenorhabditis elegans with 32 samples.

How the data were processed

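Messenger RNA was measured by RNA sequencing in 32 libraries of the nematode Caenorhabditis elegans, from 4 strains with 4 replicates each and 2 fractions of every lysate. Per the labels, day 1 adult hermaphrodites were lysed, part of each lysate was kept as total RNA, and the remainder was run over a sucrose gradient to collect the polysomes. Libraries were made from polyadenylated RNA with a stranded kit, per the labels' protocols. Salmon and DESeq2 are named in the submitters' processing notes, with no versions; the genome build, the annotation and whether counting used the strand are not given in the sources used here.

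The deposited expected counts are estimated read counts per gene, as Salmon gives them, and 15.3% of the positive values were not whole numbers. They were rounded to whole counts before any test. Every one of the 46926 rows named a gene, and 2766 rows carried only an identifier. A second deposited table holds replicate-adjusted whole numbers for the same libraries; its values were treated as a score, since how the authors adjusted them is not given in the sources used here, and it served only as an alternative input. A deposited table of sample descriptions was not used here. Gene annotation came from a table of the assembly WBcel235, which matched 44106 of the 46926 rows and 15309 of the 15939 genes tested in the lysates; a table of gene names matched 44115 identifiers. No build is given for the counts, so no coordinates are printed. Salmon divides reads between near-identical transcripts, so values of single histone, major sperm protein, collagen and F-box genes, of overlapping genes and of antisense partners are uncertain.

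Library totals ranged from 27 to 40.2 M counts, 31.4 to 40.2 M in the lysates and 27 to 36.2 M in the polysome fraction. Labels call the samples biological replicates and describe no separate cultures, so p-values measure the spread between these samples.

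Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Within each fraction, 1 fit held all 16 libraries, with the strain as the term, after filterByExpr and TMM normalisation, and genes were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. This left 15939 genes in the lysates and 15378 in the polysome fraction. Translational efficiency, the polysome level relative to the lysate, was tested as the interaction of strain and fraction over all 32 libraries and 16253 genes. The polysome fraction was compared with the lysate of the wild type in the same fit. CPM values are on TMM library sizes. A standard error was taken as the absolute log2 fold change divided by the square root of the F statistic.

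Replicate numbers come from the labels and are shared by the strains. Deviations from the group means, over 9305 genes, correlated between same-numbered libraries of different strains with r of 0.926 to 0.979 in the lysates and 0.836 to 0.958 in the polysome fraction, and with r of 0.899 to 0.950 between the fractions of 1 lysate. All 32 libraries correlated best with a library of their own number. The first principal component held 89.8% of the variance in the lysates, and the replicate number explained 98.5% of that component against 0.870% for strain; in the polysome fraction these values were 87.2%, 98.3% and 0.783%. The numbers therefore pair the samples. Because the study's description states no replicate term, the fit without it stayed the primary one. That fit leaves the pairing out, so a gene that fails to pass in it need not be unchanged. The fit with the replicate number as a block (the lysate as block for translational efficiency) is printed beside most results it changes. Counts of list members between the wild-type fractions are mostly from the fit without the block alone.

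Gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative is said to be added later. The lists were piRNA pathway, germ granule, Argonaute, 22G-RNA amplification, 26G-RNA (ERI) pathway, nuclear RNAi and chromatin, small-RNA target genes, histones, major sperm proteins, other sperm genes, oocyte and eggshell, meiotic germ line, yolk, cuticle collagens, muscle, neuron, intestine, ribosomal proteins, translation factors, mitochondrial genome, nuclear respiratory chain, proteasome, intracellular pathogen response, immune effectors, heat shock and unfolded protein, detoxification, F-box with BATH and MATH genes, and the X chromosome. A list of pseudogenes matched 3 genes in the table and was not tested. Lists were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over all lists and mutants of a readout, and again with the correlation estimated per list. Members adjusted over the list alone were counted as well.

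Genes named in the text follow a rule. For each mutant against the wild type it takes up to 8 genes with the highest and 8 with the lowest change in the lysates, and 5 and 5 in the polysome fraction, among called genes with at least 1 CPM in the higher group and no overlap between the strains. It adds up to 3 and 3 for translational efficiency and for each pair of mutants, up to 5 and 5 called with the same sign in all 3 mutants, up to 4 called members of each list described, and lotr-1. Genes with only a sequence name could be left out. Genes given with the replicate block, mostly list members and those of translational efficiency where the fit without it called 0, lie outside the rule and were chosen after the calls were seen.

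Alternatives were the replicate block, DESeq2 1.42.0 with its Wald test, RLE size factors, no filter on low counts, the replicate-adjusted table, a 2-fold minimum, only the libraries of both strains, an estimated correlation for lists, split controls for overlaps, and each library left out in turn. Overlaps between mutants were set beside 20 simulations of unchanged groups that share the wild-type libraries. Every split of 8 libraries into 4 and 4, 35 in all, was refitted for each comparison. Scripts were tested on simulated data drawn from the real means and library sizes, with 50 genes changed at each of 4 sizes. The changed genes came from those with a simulated mean of at least 50 counts, so the rates hold for such genes only. For ΔLOTR-1 against the wild type in the lysates (15939 genes), 18% of genes changed by 1 on the log2 scale and 48% of those changed by 2 were recovered without the block, and 94% and 98% with it. In the polysome fraction (15378 genes) the values were 24% and 58%, and 88% and 100%. For translational efficiency (16253 genes) they were 2% and 50%, and 58% and 96%. The block also brought false calls, 13 in the lysates, 11 in the polysome fraction and 5 for translational efficiency. Without it there were 0 in each. The false calls with the block stood beside 26, 47, 49 and 50 recovered genes in the lysates, at changes of 0.5, 1, 2 and 3. In the polysome fraction 12, 44, 50 and 50 were recovered with the block, and for translational efficiency 7, 29, 48 and 49. The 0 without the block came with fewer recovered genes, 0, 9, 24 and 35 in the lysates.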

Results

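Expression was measured in 4 strains of Caenorhabditis elegans that differ at lotr-1, which encodes a germ granule protein with LOTUS and Tudor domains. The wild type carries an epitope and GFP tag at the N terminus of lotr-1. ΔLOTR-1 carries an in-frame deletion of the gene, ΔLOTUS lacks the LOTUS domain and ΔTudor lacks the Tudor domain. Each strain had 4 replicates. Each lysate of day 1 adults gave 1 total RNA library, called lysate here, and 1 library from the polysome fraction. That fraction is meant to hold mRNAs loaded with several ribosomes. The 16 lysate libraries held 31.4 to 40.2 M counts and the 16 polysome libraries 27 to 36.2 M. Replicates differed widely within every strain. Vitellogenin mRNAs, which encode yolk proteins, took 5.27%, 5.55%, 3.59% and 1.18% of the counts in wild-type lysates 1 to 4, and ribosomal protein mRNAs took 14.8%, 14.3%, 16.9% and 21.2%.

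The targeted gene was examined first in every library. In the lysates, lotr-1 (WBGene00008385) measured 236 ± 102 CPM in the wild type and 57.6 ± 26.1 CPM in ΔLOTR-1 (SD, n = 4), with 231 ± 101 CPM in ΔTudor and 228.5 ± 76.1 CPM in ΔLOTUS. At each replicate number the ΔLOTR-1 lysate was below the wild type, at 78.4 against 305 CPM, 80.8 against 329 CPM, 43.0 against 203 CPM and 28.1 against 107 CPM. In the polysome fraction the same strains stood at 77.7 ± 34.8 CPM (wild type), 85.3 ± 39.4 CPM (ΔLOTR-1), 73.1 ± 38.4 CPM (ΔTudor) and 90.1 ± 32.4 CPM (ΔLOTUS). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the ΔLOTR-1 lysate change of -2.06 (SE 0.45) did not pass, at adjusted p = 0.127, while with the replicate block it passed at adjusted p = 2.51e-08 (SE 0.10). The polysome change of ΔLOTR-1, 0.12 (SE 0.46), passed in neither edgeR fit, with adjusted p = 1 without the block. The ΔLOTR-1 lysates therefore go with the label of the deletion strain. Lysates of ΔLOTUS and ΔTudor stood near the wild type, so this gene gives no check of their labels. The polysome libraries give no such check from this gene either. Which part of the transcript the counts cover is not given in the sources used here.

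**Figure D1:**
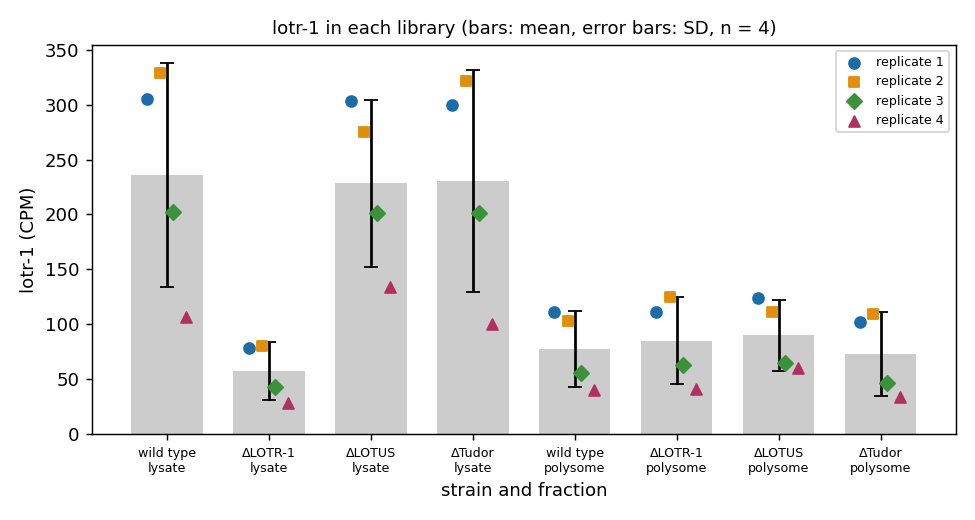
Level of lotr-1 in CPM for each strain and fraction. Bars are means of 4 replicates, error bars are SD and points are single libraries. ΔLOTR-1 stands at 57.6 CPM in the lysates against 236 CPM in the wild type, and at 85.3 against 77.7 CPM in the polysome fraction.

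The comparison of ΔLOTR-1 with the wild type asks which mRNAs differ when the gene is deleted. Each genotype is held by a single strain, so effects of lotr-1 cannot be told from other sequence differences between the strains. In the lysates the largest increases were in F55B11.6 (WBGene00044249), from 0.224 ± 0.139 to 41.6 ± 14.5 CPM, and F40D4.13 (WBGene00009572), from 0.485 ± 0.0885 to 55.9 ± 8.13 CPM (SD, n = 4). Increases of over 3 on the log2 scale were also seen for timm-17B.2, named as a subunit of the mitochondrial inner membrane translocase, from 7.1 ± 1.10 to 63.9 ± 11.8 CPM, for rnh-1.3, an RNase H gene, by 3.14 (SE 0.32), and for saeg-2, by 3.11 (SE 0.39). parn-1, the exonuclease that trims piRNA 3' ends, rose by 1.46 (SE 0.22, adjusted p = 0.00686 with edgeR's quasi-likelihood test). The largest decreases were in C27C7.1 (WBGene00007766), from 62.6 ± 22.4 to 0.688 ± 0.361 CPM, R03D7.2 (WBGene00010989), from 24.5 ± 2.80 to 0.776 ± 0.321 CPM, T16G12.3 (WBGene00011804), from 45.2 ± 7.81 to 1.45 ± 0.402 CPM, and H11L12.1 (WBGene00019189), from 6.99 ± 1.53 to 0.328 ± 0.0664 CPM.

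On the log2 scale, F55B11.6 changed by 7.49 (SE 0.65), F40D4.13 by 6.82 (SE 0.28), W09H1.4 by 3.43 (SE 0.50), C27C7.1 by -6.52 (SE 0.42), R03D7.2 by -4.99 (SE 0.45), T16G12.3 by -4.98 (SE 0.24), H11L12.1 by -4.42 (SE 0.27) and T03D3.5 by -1.87 (SE 0.34). Their adjusted p-values in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 1.49e-08 for F40D4.13 to 0.0363 for T03D3.5. In all, 43 of 15939 genes were called, 30 higher and 13 lower. The replicate block gave 1246 calls, 392 higher and 854 lower, of which 157 changed at least 2-fold, and it kept all 43. The additional calls are mostly small, with a median absolute log2 change of 0.34 over the blocked calls.

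For ΔLOTUS, which keeps the rest of the protein, the lysates showed increases of saeg-2, from 5.35 ± 1.23 to 67.0 ± 32.0 CPM, and of ceh-20, a homeobox gene of the PBC class, from 8.44 ± 1.40 to 56.0 ± 25.7 CPM (SD, n = 4). mapk-15, a MAP kinase gene, rose by 2.16 (SE 0.32), bath-38, a BATH domain gene, by 1.5 (SE 0.19), and nhr-22, a nuclear hormone receptor gene, by 1.47 (SE 0.26). R03D7.2 fell from 24.5 ± 2.80 to 0.582 ± 0.161 CPM and C27C7.1 from 62.6 ± 22.4 to 7.48 ± 0.715 CPM, while B0250.7 changed by -3.06 (SE 0.37), the noncoding RNA Y49E10.37 by -2.41 (SE 0.23) and F42A9.6 by -1.91 (SE 0.25). T16G12.3 changed by -1.25 (SE 0.20). Adjusted p-values of these genes in edgeR's quasi-likelihood test ran from 0.000235 for R03D7.2 to 0.0443 for nhr-22. The lysates of ΔLOTUS had 23 calls, 10 higher and 13 lower, against 3277 with the replicate block, 1509 higher and 1768 lower, with 407 at least 2-fold. F40D4.13, the gene of the second largest rise in ΔLOTR-1, stood at 0.440 ± 0.106 CPM in ΔLOTUS, a change of -0.14 (SE 0.23).

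In ΔTudor lysates F40D4.13 rose to 48.9 ± 9.58 CPM (SD, n = 4), a change of 6.61 (SE 0.28, adjusted p = 2.02e-08 with edgeR's quasi-likelihood test). rnh-1.3 rose by 3.36 (SE 0.33), timm-17B.2 by 1.98 (SE 0.19), C08F11.7 by 1.79 (SE 0.30) and parn-1 by 1.71 (SE 0.22). R03D7.2 changed by -3.25 (SE 0.42) and H11L12.1 by -1.47 (SE 0.24). The comparison gave 12 calls, 9 higher and 3 lower, and 2166 with the replicate block, 908 higher and 1258 lower, with 117 at least 2-fold. parn-1 was 62.0 ± 18 CPM in ΔTudor, 51.5 ± 14.6 CPM in ΔLOTR-1 and 18.4 ± 0.356 CPM in the wild type, and at 13 ± 1.09 CPM in ΔLOTUS it changed by -0.52 (SE 0.22), which passed only with the replicate block (adjusted p = 0.0219, edgeR).

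Genes named for 1 mutant were looked up in the lysates of the others. In ΔLOTR-1, C08F11.7 rose by 3.01 (SE 0.31, adjusted p = 0.000247 with edgeR's quasi-likelihood test) and ceh-20 by 1.75 (SE 0.31, adjusted p = 0.0281). In ΔLOTUS, W09H1.4 rose by 3.05 (SE 0.49, adjusted p = 0.0209). The following passed only with the replicate block, here with estimates from the fit without it. They were B0250.7 in ΔLOTR-1 (-0.70), T03D3.5 (-1.47), H11L12.1 (-0.90), C08F11.7 (1.02) and timm-17B.2 (0.69) in ΔLOTUS, and W09H1.4 (2.17), saeg-2 (2.09), C27C7.1 (-1.85), T03D3.5 (-1.42) and Y49E10.37 (1.14) in ΔTudor. Estimates that passed in neither fit were 0.93 in ΔLOTUS and 0.89 in ΔTudor for F55B11.6, -0.16 in ΔLOTUS for rnh-1.3, and -0.46 and 0.03 in ΔTudor for T16G12.3 and ceh-20. In ΔLOTR-1 and ΔTudor they were 0.56 and 0.37 for mapk-15, 0.27 and 0.18 for bath-38, 0.12 and 0.24 for nhr-22 and -0.07 and -0.02 for F42A9.6, with 0.20 for Y49E10.37 in ΔLOTR-1 and -0.24 for B0250.7 in ΔTudor.

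Direct tests between mutants asked where the domain deletions differ from the full deletion. F40D4.13 was lower in ΔLOTUS than in ΔLOTR-1 by -6.96 (SE 0.28) and lower than in ΔTudor by -6.75 (SE 0.28), and rnh-1.3 was lower by -3.30 (SE 0.33) and -3.52 (SE 0.33). F55B11.6 was lower in both domain deletions than in ΔLOTR-1, by -6.56 (SE 0.62) in ΔLOTUS and -6.59 (SE 0.62) in ΔTudor. T16G12.3 was higher than in ΔLOTR-1 by 3.72 (SE 0.22) and 4.52 (SE 0.23), and C27C7.1 by 3.43 (SE 0.37) and 4.67 (SE 0.39). parn-1 was lower in ΔLOTUS by -1.98 (SE 0.22) against ΔLOTR-1 and -2.23 (SE 0.22) against ΔTudor, whereas ceh-20 was higher in ΔLOTUS than in ΔTudor by 2.66 (SE 0.32). Every one of these passed edgeR's quasi-likelihood test, with adjusted p between 1.22e-08 and 0.00208. In all, 28 genes differed between ΔLOTUS and ΔLOTR-1 (6 higher, 22 lower), 15 between ΔTudor and ΔLOTR-1 (6 higher, 9 lower) and 19 between ΔLOTUS and ΔTudor (3 higher, 16 lower). The block raised these counts to 217, 84 and 135.

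**Figure D2:**
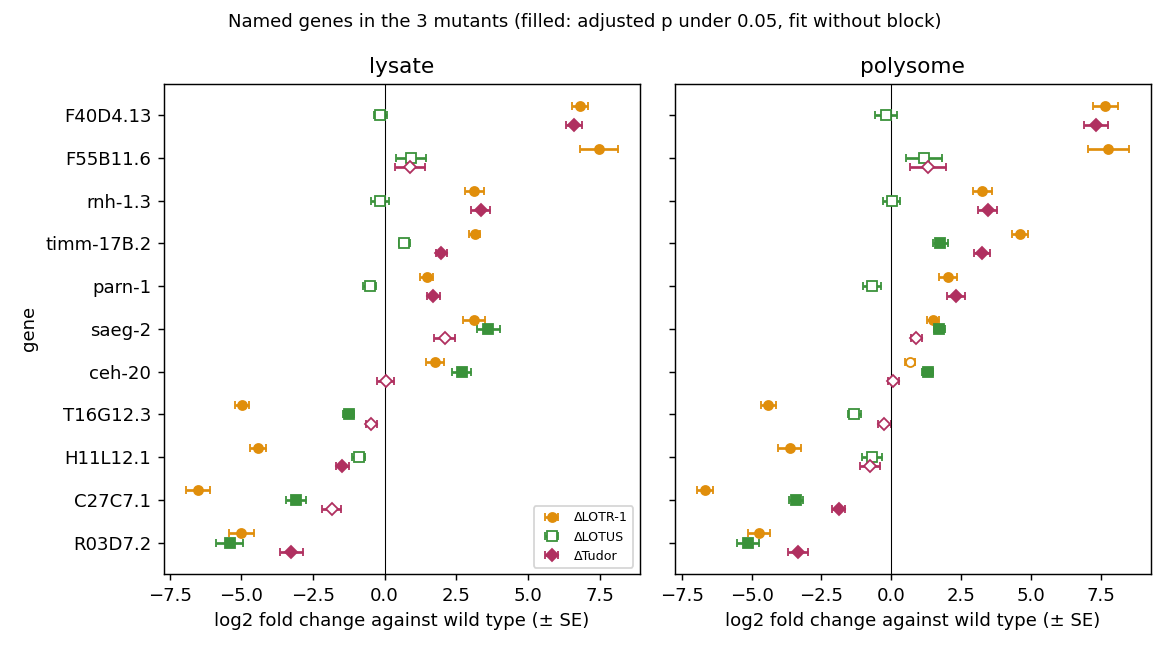
Log2 fold change of 11 genes in each mutant against the wild type, by fraction. Points are estimates, error bars are SE from fits over 4 replicates per strain, and filled points have an adjusted p under 0.05. F40D4.13 and rnh-1.3 lie far above 0 in ΔLOTR-1 and ΔTudor and near 0 in ΔLOTUS.

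Lists of ribosomal protein, translation factor, nuclear respiratory chain and proteasome mRNAs had medians below 0 in the lysates of all 3 mutants. The 3 comparisons share the wild-type libraries, so they are not independent. The 81 ribosomal protein mRNAs had median log2 changes of -0.34 in ΔLOTR-1, -0.40 in ΔLOTUS and -0.40 in ΔTudor, with camera adjusted p = 4.35e-49, 2.92e-52 and 1.2e-61, and adjusted p = 0.275, 0.262 and 0.195 with an estimated correlation. In the blocked fit 72, 78 and 79 of the 81 fell, among them rpl-43 by -0.44 in ΔLOTR-1 and -0.50 in ΔLOTUS and rla-2 by -0.44 in ΔLOTR-1 and -0.46 in ΔTudor. rpl-42 went the other way, rising by 1.39 in ΔLOTR-1 and 1.19 in ΔTudor in the blocked fit. Without the block, edgeR called 0 of the 81 over all genes in each mutant, with 43, 64 and 70 at an unadjusted p under 0.05 and 5, 19 and 8 called by DESeq2. Adjusted over the list alone, 0, 58 and 65 were lower.

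The 40 translation factor mRNAs had medians of -0.17, -0.24 and -0.26 in ΔLOTR-1, ΔLOTUS and ΔTudor (camera adjusted p = 3.37e-09, 1.72e-09 and 7.28e-13, and adjusted p = 0.187, 0.187 and 0.181 with an estimated correlation). ife-5, an eIF4E isoform, changed by -0.55 in ΔLOTR-1 and -0.60 in ΔLOTUS with the replicate block. The 41 nuclear genes of the respiratory chain had medians of -0.17, -0.27 and -0.28 (camera adjusted p = 6.59e-12, 5.17e-17 and 3.53e-19, and adjusted p = 0.315, 0.195 and 0.187 with an estimated correlation). With the block 15, 31 and 28 of them fell and 0 rose, for example atp-4 by -0.37, -0.46 and -0.41 and cox-6C by -0.37, -0.45 and -0.41; the edgeR fit without the block called 0, with 6, 14 and 11 at an unadjusted p under 0.05 and 1, 5 and 3 called by DESeq2. The 33 proteasome mRNAs had medians of -0.20, -0.23 and -0.25 (camera adjusted p = 1.89e-08, 1.17e-08 and 1.58e-11, and adjusted p = 0.933, 0.933 and 0.797 with an estimated correlation), and 15, 20 and 20 fell with the block, pbs-1 by -0.29, -0.36 and -0.36.

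Cuticle collagens, the structural proteins of the exoskeleton, had medians below 0 in the domain deletions. The 148 collagen mRNAs had lysate medians of -0.48 in ΔLOTUS and -0.35 in ΔTudor (camera adjusted p = 0.00685 and 0.00329, and adjusted p = 0.998 with an estimated correlation in both), and -0.17 in ΔLOTR-1, which did not pass (0.198). In the blocked fit 61 fell in ΔLOTUS and 18 in ΔTudor, among them col-47 by -2.95 and -2.13 and col-110 by -2.02 and -1.13. In the same lysates the share of counts in collagen mRNAs varied within the wild type from 3.49% in replicate 1 to 6.22% in replicate 4. Histone mRNAs (54) had medians of -0.28, -0.31 and -0.31 in ΔLOTR-1, ΔLOTUS and ΔTudor (camera adjusted p = 0.00959, 0.0358 and 0.0101, and adjusted p = 0.359, 0.62 and 0.359 with an estimated correlation). The 32 intestinal genes had medians of -0.18 in ΔLOTUS and -0.14 in ΔTudor (camera adjusted p = 0.013 and 0.0268, and adjusted p = 0.998 with an estimated correlation), and the metallothionein mtl-2 changed by -0.55 and -0.51 with the block.

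**Figure D3:**
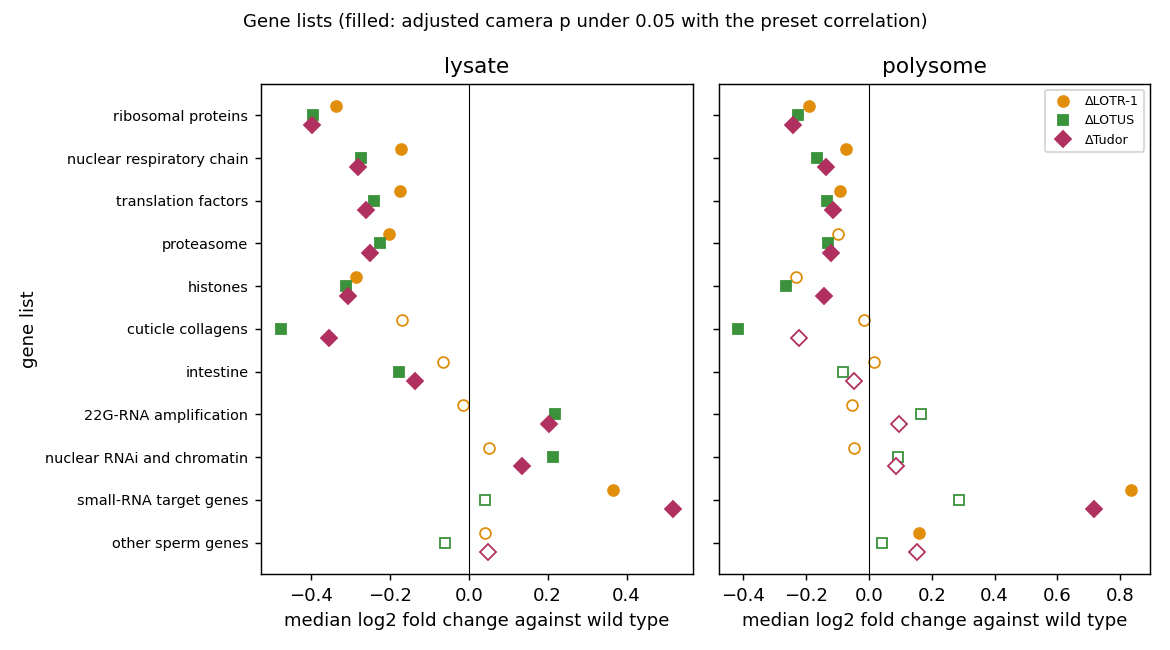
Median log2 fold change of 11 gene lists in each mutant against the wild type, by readout. Filled points have an adjusted camera p under 0.05 at the preset correlation, and every lysate call shown is lost with an estimated correlation. Ribosomal protein medians are -0.34, -0.40 and -0.40 in the lysates with TMM scaling, and they stay below 0 with RLE scaling.

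Of the lists of small-RNA genes, 4 passed upward in the lysates of at least 1 mutant at the preset correlation, and none with an estimated one. The 19 genes of 22G-RNA amplification had lysate medians of 0.22 in ΔLOTUS and 0.20 in ΔTudor (camera adjusted p = 0.0145 and 0.0442, and adjusted p = 0.998 with an estimated correlation), and -0.01 in ΔLOTR-1. Blocking by replicate, 11 rose in ΔLOTUS, and 7 rose and 1 fell in ΔTudor, among them the RNA-dependent RNA polymerase genes ego-1 by 0.56 and 0.52 and rrf-1 by 0.64 and 0.69. The 18 nuclear RNAi and chromatin genes had medians of 0.21 and 0.14 in these strains (camera adjusted p = 0.0143 and 0.0236, and adjusted p = 0.998 with an estimated correlation), and mes-3 of the Polycomb complex rose by 0.75 and 0.71 with the block. The 13 genes of the 26G-RNA pathway had a median of 0.27 in ΔTudor (camera adjusted p = 0.0358, and adjusted p = 0.933 with an estimated correlation), with the Dicer gene dcr-1 rising by 0.44 in the blocked fit. Genes known as targets of small RNAs, 10 in the lysates, had medians of 0.37 in ΔLOTR-1 and 0.52 in ΔTudor (camera adjusted p = 0.00803 and 0.00329, and adjusted p = 0.181 with an estimated correlation in both). With the block 4 rose in each, bath-45 by 1.05 and 0.95 and xol-1, the switch gene of sex determination, by 1.48 and 1.33; in ΔLOTUS their median was 0.04 while the test leaned lower, and it did not pass (0.683).

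The large lysate changes of ΔLOTR-1 were also measured in its polysome fraction. F55B11.6 rose by 7.77 (SE 0.74), F40D4.13 by 7.67 (SE 0.43) and timm-17B.2 from 5.96 ± 1.91 to 145 ± 37.3 CPM (SD, n = 4), while C27C7.1 changed by -6.68 (SE 0.29), R03D7.2 by -4.74 (SE 0.39), T16G12.3 by -4.40 (SE 0.27) and H11L12.1 by -3.64 (SE 0.40). In ΔLOTUS, timm-17B.2 rose to 20.2 ± 4.38 CPM, saeg-2 by 1.72 (SE 0.20) and ceh-20 by 1.31 (SE 0.19), and R03D7.2 and C27C7.1 changed by -5.14 (SE 0.40) and -3.40 (SE 0.25). In ΔTudor, F40D4.13 rose by 7.34 (SE 0.43), rnh-1.3 by 3.46 (SE 0.34), timm-17B.2 to 57.3 ± 12.4 CPM and parn-1 by 2.30 (SE 0.32), and R03D7.2 changed by -3.33 (SE 0.37). Adjusted p-values of these genes in edgeR's quasi-likelihood test lay between 3.42e-08 and 0.018. Of 15378 genes, 34 were called in ΔLOTR-1 (29 higher, 5 lower), 9 in ΔLOTUS (3 higher, 6 lower) and 15 in ΔTudor (12 higher, 3 lower), against 97, 162 and 35 with the replicate block. Between mutants 21, 16 and 11 genes differed in the polysome fraction (ΔLOTUS and ΔLOTR-1, ΔTudor and ΔLOTR-1, ΔLOTUS and ΔTudor), and 74, 32 and 47 with the block.

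Ribosomal protein mRNAs again had medians below 0 in the polysome fraction, at -0.19, -0.22 and -0.24 in ΔLOTR-1, ΔLOTUS and ΔTudor (camera adjusted p = 1.16e-24, 1.15e-28 and 3.16e-38, and adjusted p = 0.646, 0.535 and 0.397 with an estimated correlation). DESeq2 called 0 of the 81 members in each mutant. The blocked fits called 20, 98 and 5 genes lower in all, so most members did not pass in ΔLOTR-1 and ΔTudor. In the blocked fit rpl-42 rose by 2.58 in ΔLOTR-1 and by 2.06 in ΔTudor. Collagens had a median of -0.41 in ΔLOTUS (camera adjusted p = 0.00146, and adjusted p = 0.997 with an estimated correlation), and 22 of 146 fell with the block, led by bli-1 at -2.32 and col-46 at -2.01, both cuticle genes. Small-RNA target genes, 7 in this fraction, had medians of 0.83 in ΔLOTR-1 and 0.72 in ΔTudor (camera adjusted p = 1.65e-05 and 0.00514, and adjusted p = 0.272 and 0.397 with an estimated correlation), with E01G4.5 up by 1.53 in ΔLOTR-1 and 1.38 in ΔLOTUS in the blocked fit. Sperm genes other than major sperm proteins had a median of 0.16 in ΔLOTR-1 (camera adjusted p = 0.00425, and adjusted p = 0.997 with an estimated correlation), and fog-3, a gene of the sperm fate, rose by 1.40 with the block.

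Translational efficiency asks whether a mutant moves an mRNA in the polysome fraction beyond its change in the lysate. With edgeR's quasi-likelihood test 0 of 16253 genes passed in each mutant, with 111, 103 and 92 genes at an unadjusted p under 0.05 in ΔLOTR-1, ΔLOTUS and ΔTudor, and DESeq2 called 5, 6 and 7. With the lysate as block 9, 0 and 1 genes passed. Those of ΔLOTR-1 included lotr-1 itself at 2.16 (SE 0.15, adjusted p = 4.93e-07, edgeR), enu-3.6 at 1.00 (adjusted p = 0.000684), timm-17B.2 at 1.45 (adjusted p = 0.0124), enu-3.1 at 0.65 (adjusted p = 0.0441), Y45F10C.6 at 1.80 (adjusted p = 0.0124) and Y39B6A.69 at 2.60 (adjusted p = 0.00765), and 3 genes named only by an identifier. The gene of ΔTudor was enu-3.6 at 0.98 (adjusted p = 0.00189). Ribosomal protein mRNAs had medians of 0.12, 0.15 and 0.13 (camera adjusted p = 2.92e-07, 4.57e-11 and 9.08e-10, and adjusted p = 0.995 with an estimated correlation), and nuclear respiratory chain mRNAs 0.10, 0.09 and 0.11 (camera adjusted p = 0.00257, 0.00681 and 0.00175, and adjusted p = 0.995 with an estimated correlation).

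The wild-type fractions were compared to ask which mRNAs are relatively abundant on polysomes. Ribosomal protein mRNAs were higher in the polysome fraction, with a median of 1.18 (camera adjusted p = 1.58e-71, and adjusted p = 0.0379 with an estimated correlation), and 75 of 81 passed upward and 1 downward, rpl-14 by 1.42 (SE 0.13) and rps-13 by 1.36 (SE 0.13). Nuclear respiratory chain mRNAs had a median of 0.90, with 29 of 41 higher and 0 lower in edgeR (31 at an unadjusted p under 0.05), and adjusted p = 0.0208 with an estimated correlation. The meiotic list had a median of -1.14 with 24 of 44 lower, among them daz-1 by -2.74 (SE 0.49) and gld-1, a translational repressor, by -2.31 (SE 0.56), although its camera adjusted p of 3.26e-12 became adjusted p = 0.59 with an estimated correlation. Small-RNA target genes had a median of -1.48, with K02E2.6 at -2.33 (SE 0.28) and bath-45 at -2.51 (SE 0.36), and kept adjusted p = 0.00676 with an estimated correlation. The 22G-RNA amplification, Argonaute and oocyte lists had medians of -1.16, -1.07 and -1.38 (camera adjusted p = 5.31e-06, 6.79e-05 and 0.000133, and adjusted p = 0.59, 0.287 and 0.69 with an estimated correlation), with mut-16 at -1.78 (SE 0.38), alg-5 at -2.53 (SE 0.54) and nos-2 at -3.39 (SE 1.04). The piRNA Argonaute gene prg-1 changed by -1.34 (SE 0.25). In all 3139 of 16253 genes were called, 1559 higher and 1580 lower, against 9028 with the lysate as block. The median over all genes was 0.066 with TMM and -0.049 with RLE scaling, which are small beside these list medians. Mitochondrial-genome mRNAs, listed in advance as a check of fraction purity, had medians of 0.047 with TMM and -0.066 with RLE scaling. Relative to other mRNAs they were thus not depleted from the polysome fraction. The check therefore gives no sign of purity, and whether a level there means loading with ribosomes was not tested.

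Several genes changed the same way in more than 1 mutant. In the lysates 58 genes were called in at least 1 mutant, and R03D7.2 and WBGene00014947 were lower in all 3; in the polysome fraction timm-17B.2 was higher and C27C7.1, R03D7.2 and T03D3.5 were lower in all 3. ΔLOTR-1 shared 11 lysate calls of the same sign with ΔLOTUS and 9 with ΔTudor, and ΔLOTUS shared 2 with ΔTudor. Independent lists of these lengths would share 0.0188 higher and 0.0106 lower genes in the first pair. The 3 comparisons use the same wild-type libraries, and 20 simulations of unchanged strains against them gave 0 shared calls, drawn without the replicate numbers that the real strains share. Strains without a change give hardly any calls to share, so this 0 says nothing about sharing through common controls. When the wild-type libraries were split between the mutants, 4.17, 4.17 and 1 shared calls were left on average, and the lists themselves shrank from 43, 23 and 12 calls to 20, 10 and 5.33 in ΔLOTR-1, ΔLOTUS and ΔTudor. With the replicate block the shared calls numbered 908, 884 and 1747, where independent lists would share 37.1 higher and 94.7 lower, 22.3 and 67.4, and 86 and 139.5. Split controls left 107, 80.2 and 356 of them on average, but halving the wild type also shortened the lists, from 1246, 3277 and 2166 calls to 258.5, 1581 and 687 in ΔLOTR-1, ΔLOTUS and ΔTudor, so in neither fit does the fall measure sharing through common controls. Fold changes were also correlated across genes, which are not independent replicates. Without the block, r in the lysates was 0.63, 0.69 and 0.69 and the covariance 0.156, 0.134 and 0.160. The simulated values for that fit, r of 0.50 in each pair and a covariance of 0.309, 0.310 and 0.311, hold a replicate spread that cancels between the real, same-numbered libraries, so they give no usable comparison. With split controls, which also differ in replicate numbers, r was 0.01, 0.02 and 0.03 and the covariance -0.185, -0.178 and -0.179. In the blocked lysate fits r was 0.63, 0.70 and 0.66 against 0.51, 0.51 and 0.50 simulated, with a covariance of 0.151, 0.140 and 0.147 against 0.0398, 0.0398 and 0.0390. Split controls lowered these to r of 0.28, 0.30 and 0.29 and a covariance of 0.0939, 0.0931 and 0.0912. In the blocked polysome fits r was 0.49, 0.54 and 0.55 against 0.50 simulated in each pair, with a covariance of 0.0914, 0.0832 and 0.0876 against 0.050, 0.0493 and 0.0493. Split controls lowered these to r of 0.05, 0.05 and 0.04 and a covariance of 0.0133, 0.0117 and 0.0108.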

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

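The tests of the lotr-1 pattern were chosen after its values were seen.

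In ΔLOTR-1, lotr-1 was low in the lysates and not in the polysome libraries. In the lysates ΔLOTR-1 measured 57.6 ± 26.1 CPM against 236 ± 102 CPM in the wild type (SD, n = 4), and in the polysome fraction 85.3 ± 39.4 against 77.7 ± 34.8 CPM. Polysome libraries taken from another strain were left open by a first test. All 41 genes called in ΔLOTR-1 lysates and tested in the polysome fraction had the same sign there (100%, exact 95% interval 91.4% to 100%), but 90.2% also had it in the polysome fraction of ΔLOTUS and 90.2% in that of ΔTudor, so this sign does not tell the mutants apart. Genes that differed in the lysates between ΔLOTR-1 and each other strain argue against it. In each ΔLOTR-1 polysome library 39 to 41 of 41 kept the sign of the lysates against the same-numbered wild-type library, 27 of 27 against ΔLOTUS and 14 or 15 of 15 against ΔTudor, the lowest share being 93.3% (68.1% to 99.8%). A single odd library was left open by a first test, in which 2 of 4 polysome libraries lay above the highest lysate library, and argued against by a comparison within replicate numbers, where the polysome to lysate ratio exceeded that of the wild type by more than 1 on the log2 scale at 4 of 4 numbers (1.96 to 2.42). A deletion that leaves a stretch of the transcript counted differently in the fractions could give such values and stays open, as does a biological difference in what the deletion leaves on polysomes, and neither was tested. A raised polysome to lysate ratio in ΔLOTR-1 was not confined to lotr-1. With the lysate as block, 9 genes passed upward and 0 downward, lotr-1 among them. Of these, Y39B6A.69 measured 5.79 CPM in the lysates and 10.6 CPM in the polysome fraction, against 0.523 and 0.146 CPM in the wild type. Across ΔLOTR-1 polysome replicates 1 to 4 it ran with lotr-1, at 13.8, 16.1, 7.55 and 4.99 CPM against 112, 125, 63.3 and 41.6 CPM. Polysome lotr-1 also fell over these numbers in the wild type, from 111 to 40.6 CPM. timm-17B.2, also among the 9, ran at 100, 172, 130 and 180 CPM. Reads shared between genes were not tested, so the 9 need not be separate cases.

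A library stood far from the others in 5 of 152 groups of 4 values, where chance gives about 1 in 20. The polysome library of ΔLOTR-1 replicate 3 held 34.2 M counts where the others held 33.5 to 33.6 M. Replicate 4 of the same group had counts for 19420 genes against 17711 to 17765, of which 843 had counts in that library only, 1251 counts in all with a median of 1, where other polysome libraries had 46 to 154 such genes. Yolk mRNAs took 2.91% of the counts in the ΔLOTUS lysate replicate 4 against 5.27% to 5.63%. The rule ignores replicate numbers, and replicate 4 also had the lowest yolk share in the other lysates, at 1.18% (wild type), 1.98% (ΔLOTR-1) and 2.28% (ΔTudor). C27C7.1 stood at 13.7 CPM in ΔTudor lysate replicate 4 against 19.2 to 19.5 CPM, and H11L12.1 at 0.616 CPM in ΔLOTR-1 polysome replicate 3 against 0.176 to 0.240 CPM. Lysate replicate 4 was also lowest in C27C7.1 in the wild type (38.9 CPM) and ΔLOTUS (6.57 CPM), but highest in ΔLOTR-1 (1.17 CPM).

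Mutants differed from each other in direct edgeR tests, with 28 genes between ΔLOTUS and ΔLOTR-1, 15 between ΔTudor and ΔLOTR-1 and 19 between ΔLOTUS and ΔTudor in the lysates, and 21, 16 and 11 in the polysome fraction. The effect of ΔLOTR-1 differed between polysome fraction and lysate for 9 genes and that of ΔTudor for 1 gene with the lysate as block.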

How the results depend on the processing

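Tests chosen after the data were seen are those that leave out libraries with the replicate block kept, the estimated correlation with the block, and the block for the overlap of mutants.

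Named genes kept their direction in 1146 of 1146 recomputed values, with 957 on the same side of the threshold and 189 no longer past it. The naming rule took mainly genes called in these same libraries, so a reversal was unlikely from the start and the kept direction is weak support. All values stayed called with the replicate block (87 of 87), DESeq2 (87 of 87) and the replicate-adjusted input (69 of 69); 134 of the losses came from leaving out 1 library, 40 from using only the 8 libraries of both strains, 10 from no filter and 5 from RLE. The block also changed calls of single genes, which are given where they are named. Below, unless a strain is named, values follow the order ΔLOTR-1, ΔLOTUS and ΔTudor against the wild type, then ΔLOTUS against ΔLOTR-1, ΔTudor against ΔLOTR-1 and ΔLOTUS against ΔTudor. The cause of the moves was not tested, except that the block removes the spread between replicate numbers.

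ΔLOTR-1 in the lysates had 43 calls without the block, 1246 with the replicate block, 126 with DESeq2, 1949 with the adjusted table and 14 with only the 8 libraries of both strains, which are fewer samples. ΔLOTUS in the lysates had 23, 3277, 183, 3684 and 6 in the same order, and ΔTudor in the lysates 12, 2166, 87, 2719 and 2. The contrasts between mutants had 28, 15 and 19 calls there, 217, 84 and 135 with the replicate block and 66, 51 and 57 with DESeq2. ΔLOTR-1 in the polysome fraction had 34, 97, 63, 137 and 15 calls in the order of the lysates, ΔLOTUS in the polysome fraction 9, 162, 41, 344 and 2, and ΔTudor in the polysome fraction 15, 35, 33, 77 and 5. The contrasts between mutants had 21, 16 and 11 calls there, 74, 32 and 47 with the replicate block and 47, 35 and 38 with DESeq2. For translational efficiency, 0 calls each in edgeR (111, 103 and 92 at an unadjusted p under 0.05) became 9, 0 and 1 with the lysate as replicate block, 5, 6 and 7 with DESeq2 and 16, 9 and 7 with the adjusted table. The 3139 calls between the wild-type fractions became 9028 with the block, 9268 with the adjusted table and 1985 with a 2-fold minimum. RLE and no filter stayed within 1.5 times of every count.

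List calls fell from 30 in the lysates, 19 in the polysome fraction and 12 in translational efficiency to 0 in each with camera and an estimated correlation, also with the replicate block; with the block at the preset correlation they were 36, 31 and 39. Genes changed the same way and shared by mutants, with no fold minimum, rose from 18 to 2019 with the block. Shared lysate calls of 11, 9 and 2 fell to 4.17, 4.17 and 1 with split controls, and blocked ones of 908, 884 and 1747 to 107, 80.2 and 356, while halving the wild type also cut the lists, to 20, 10 and 5.33 calls without the block and 258.5, 1581 and 687 with it. As a log2 ratio of mean CPM, not the edgeR estimate, the change of lotr-1 in ΔLOTR-1 lysates was -2.03 on TMM sizes and -1.94 on raw totals.

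Leaving out 1 library gave ranges, without the block, of 30 to 45, 12 to 25, 7 to 9, 16 to 26, 5 to 16 and 14 to 20 calls in the lysates, 25 to 31, 4 to 9, 9 to 12, 17 to 22, 12 to 16 and 8 to 11 in the polysome fraction, 0 to 2, 0 to 0 and 0 to 0 for translational efficiency and 1773 to 2694 between wild-type fractions. With the block they were 246 to 1163, 2012 to 3254, 912 to 1638, 102 to 449, 49 to 86 and 78 to 121 in the lysates and 57 to 91, 42 to 186, 21 to 33, 43 to 76, 22 to 27 and 26 to 46 in the polysome fraction.

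The counts moved by over 1.5 times without the block as follows. ΔLOTUS in the lysates gave 12 and 13 without wild-type replicates 1 and 2 and 12 and 12 without ΔLOTUS replicates 1 and 2. ΔTudor in the lysates gave 7, 7 and 7 without wild-type replicates 1, 2 and 3 and 7 and 7 without ΔTudor replicates 1 and 2. ΔLOTUS against ΔLOTR-1 in the lysates gave 16 without ΔLOTUS replicate 3. ΔTudor against ΔLOTR-1 in the lysates gave 5, 8 and 9 without ΔTudor replicates 1, 2 and 3 and 9 without ΔLOTR-1 replicate 2. ΔLOTUS in the polysome fraction gave 4 without wild-type replicate 2 and 5 and 4 without ΔLOTUS replicates 2 and 3. ΔTudor in the polysome fraction gave 9 without wild-type replicate 3. ΔLOTR-1 in translational efficiency gave 2 without wild-type replicate 2. The comparison of wild-type fractions gave 2008, 1773 and 2088 without wild-type replicates 1, 2 and 3.

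With the replicate block the moves of this size were as follows. ΔLOTR-1 in the lysates gave 361, 653 and 479 without wild-type replicates 1, 2 and 4 and 246 and 434 without ΔLOTR-1 replicates 1 and 4. ΔLOTUS in the lysates gave 2172 and 2012 without ΔLOTUS replicates 1 and 3. ΔTudor in the lysates gave 1295 and 1315 without wild-type replicates 1 and 3 and 912 and 1236 without ΔTudor replicates 2 and 3. ΔLOTUS against ΔLOTR-1 in the lysates gave 102 and 115 without ΔLOTR-1 replicates 1 and 2 and 117, 449, 121 and 141 without ΔLOTUS replicates 1, 2, 3 and 4. ΔTudor against ΔLOTR-1 in the lysates gave 51 and 55 without ΔTudor replicates 1 and 2 and 49 without ΔLOTR-1 replicate 1. ΔLOTUS against ΔTudor in the lysates gave 78 and 80 without ΔTudor replicates 1 and 3 and 86 and 87 without ΔLOTUS replicates 1 and 3. ΔLOTR-1 in the polysome fraction gave 63 and 64 without wild-type replicates 1 and 3 and 57 without ΔLOTR-1 replicate 1. ΔLOTUS in the polysome fraction gave 42 and 58 without wild-type replicates 3 and 4 and 62 and 75 without ΔLOTUS replicates 3 and 4. ΔTudor in the polysome fraction gave 21, 23 and 23 without wild-type replicates 1, 2 and 3 and 23 without ΔTudor replicate 2. ΔLOTUS against ΔLOTR-1 in the polysome fraction gave 43 without ΔLOTR-1 replicate 1 and 49 without ΔLOTUS replicate 3. ΔLOTUS against ΔTudor in the polysome fraction gave 26 without ΔTudor replicate 1 and 28, 27 and 31 without ΔLOTUS replicates 1, 2 and 3.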

Other observations

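Tests of the genes shared by the mutants with the wild-type strain as their source were chosen after the result was seen, and the tests of ribosomal protein mRNAs and of the chromosome of lotr-1 were not.

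Other gene lists give a wider view of the lysates, with edgeR members and camera tests as before. The 412 matched F-box, BATH and MATH genes, of which 292 were tested, had medians of 0.03, 0.10 and 0.20 in ΔLOTR-1, ΔLOTUS and ΔTudor, and the list passed in ΔLOTR-1 and ΔTudor (camera adjusted p = 0.0358 and 0.000996, and adjusted p = 0.998 and 0.901 with an estimated correlation). In the blocked fit fbxb-41 rose by 3.34 in ΔLOTR-1, and fbxb-7 changed by -1.27, -1.11 and -1.24 in the 3 mutants. Detoxification genes had a median of 0.12 in ΔLOTR-1 (camera adjusted p = 0.0338, and adjusted p = 0.998 with an estimated correlation) and of -0.02 and -0.01 in ΔLOTUS and ΔTudor, which did not pass and turn positive with RLE scaling, while gst-24 changed by -0.71, -0.75 and -0.63 in the 3 mutants with the block. Genes of the mitochondrial genome had a lysate median of -0.12 in ΔLOTR-1 (camera adjusted p = 0.0346, and adjusted p = 0.998 with an estimated correlation), medians of -0.06 in ΔLOTUS and 0.01 in ΔTudor, which did not pass, and a polysome median of 0.21 in ΔLOTUS (camera adjusted p = 0.00415, and adjusted p = 0.941 with an estimated correlation). The intracellular pathogen response list had medians of 0.19, 0.28 and 0.23 and missed the threshold in all 3 mutants (camera adjusted p = 0.0527 in each).

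The lists in this paragraph did not pass in the lysates. Medians in ΔLOTR-1, ΔLOTUS and ΔTudor were -0.01, -0.10 and -0.10 for major sperm proteins, 0.04, -0.06 and 0.05 for other sperm genes, -0.03, 0.10 and 0.05 for the meiotic germ line, 0.06, 0.14 and -0.08 for yolk, -0.01, -0.05 and -0.17 for muscle and -0.04, -0.06 and -0.10 for neuron genes. Oocyte and eggshell genes had medians of -0.12, 0.03 and -0.01, the last of which turns positive with RLE scaling. The piRNA pathway had medians of -0.10, -0.08 and -0.06, against a mean above 0 in ΔLOTR-1 and ΔTudor, where parn-1 was the called member. Germ granule medians were -0.11, -0.02 and -0.07, the middle one positive with RLE scaling, and Argonaute medians were -0.00, 0.08 and 0.07. Immune effectors had medians of -0.00, -0.09 and -0.11, heat shock genes 0.05, 0.05 and -0.02, and the X chromosome 0.01, -0.01 and -0.02, with changes of sign under RLE in the first and second. In the blocked fit znfx-1, the Z granule helicase gene, rose by 0.34, 0.48 and 0.49.

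In the wild type, 9 of 32 intestinal genes were higher in the polysome fraction than in the lysate and 0 lower in edgeR (11 at an unadjusted p under 0.05, and 23 higher with the block), with a median of 0.69 (camera adjusted p = 4.66e-05, and adjusted p = 0.59 with an estimated correlation). Of the muscle genes 9 of 26 were higher, with a median of 0.60 (camera adjusted p = 0.012, and adjusted p = 0.69 with an estimated correlation). Examples are the saposin gene spp-5 at 1.48 (SE 0.16) and the troponin C gene pat-10 at 1.32 (SE 0.34). Major sperm protein genes had a median of 1.28, with 0 called in edgeR (0 at an unadjusted p under 0.05) and 28 of 30 higher with the block. Genes of the piRNA pathway had a median of -0.45 with 8 of 20 lower, and of the germ granule -0.59 with 5 of 22 lower and 1 higher, znfx-1 by -1.28 (SE 0.29) among them.

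Ribosomal protein mRNAs had medians below 0 in the lysates of all 3 mutants, and 3 technical explanations were tested. The list passed at the preset correlation, but with adjusted p = 0.275, 0.262 and 0.195 with an estimated correlation it did not, and edgeR without the block called 0 of the 81 members (43, 64 and 70 at an unadjusted p under 0.05, and 5, 19 and 8 called by DESeq2). A shift of mutant animals along the axis that separates the replicate numbers predicted at most 5.92% of the median change, which argues against it. Leaving out each wild-type library in turn kept the highest median over the mutants at -0.304 in the blocked fit, which argues against a single wild-type library. A shift of all abundant mRNAs stays open, since the medians lay -0.216, -0.230 and -0.158 below those of 125 other genes of the same CPM, and the third value falls short of the 0.2 asked for in advance. All 3 comparisons use the same wild-type libraries, so a joint shift of those libraries could move every median. Such a shift stays open, as does a biological difference between the strains that may underlie part of the change, and neither was tested.

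Of 18 genes changed at least 2-fold the same way in more than 1 mutant in the lysates, 10 (55.6%, exact 95% interval 30.8% to 78.5%) also differed between mutants in a direct test, which argues against a peculiarity of the wild-type strain as the whole cause. The others did not pass that test, among them R03D7.2 and WBGene00014947, lower in every mutant, so for them such a peculiarity stays open. Sequence variants linked to lotr-1 could not be excluded, since 13 of the 18 genes had a chromosome assigned, too few for the check to count. The odds ratio of lying on the chromosome of lotr-1 was 1.55 (0.274 to 6.03, Fisher's exact p = 0.455). Variants elsewhere in the genome were not tested, and each genotype is held by a single strain. With no fold minimum the genes shared by mutants numbered 18 without the block and 2019 with the replicate block.

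Splits of the samples showed the structure of the replicates. For each mutant and each pair of mutants in both fractions, 2 of 35 splits into 4 and 4 gave at least the real count, the real split among them, so chance cannot be excluded at 0.05; the other was always replicates 1 and 2 against replicates 3 and 4, which called 9944, 9768, 10402, 9177, 10251 and 10160 genes in the lysates and 7186, 8238, 8754, 6539, 7650 and 8524 in the polysome fraction. So many calls point to a structure of the samples that follows the replicate number. The real counts were 43, 23, 12, 28, 15 and 19 in the lysates and 34, 9, 15, 21, 16 and 11 in the polysome fraction, and every other split gave at most 1. Of the 8 splits that part every pair of same-numbered libraries, the highest other gave 1, and 8 are too few for a share under 0.05. With the replicate block the highest other split gave 2 against real counts of 1246, 3277, 2166, 217, 84 and 135 in the lysates, and 18 against 162 for ΔLOTUS in the polysome fraction, where the remaining comparisons gave 0 against 97, 35, 74, 32 and 47. For translational efficiency edgeR called 0 genes without the block (111, 103 and 92 at an unadjusted p under 0.05, and 5, 6 and 7 with DESeq2), which 35 of 35 splits must reach, so that count says nothing about chance. With the lysate as block the real counts were 9, 0 and 1 in ΔLOTR-1, ΔLOTUS and ΔTudor, and every other split gave 0. In the wild type 2 of 35 splits reached the 3139 calls between fractions, the other at 5438, and with the lysate as block the real split called 9028 against 0.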
